A study of Mus musculus with 3 samples.

How the data were processed

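Libraries came from mouse mammary epithelial cells, 1 per genotype (Control, Pik3caHR and Pik3caHR_Kdm6aKO), each made 2 weeks after adeno-Cre and sorted for GFP. The authors ran Cell Ranger ATAC and Seurat on genome build mm10, per the submitters' processing notes, with versions and settings not given in the sources used here. The deposited matrices of Control and Pik3caHR hold a count for each peak and cell barcode, and the barcodes had been filtered as deposited. Entries were even in 91.5% and 91.2% of cases, so that both ends of a fragment appear to be counted, and every interval for counting error was computed on counts divided by 2. Peaks differ in number and edges between the deposited files, so each library was treated as having its own. Levels of Pik3caHR_Kdm6aKO were not analysed here, and its barcodes and peaks were.

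Depth differed between libraries. Control cells had a median of 17771 counts and Pik3caHR cells 13409, and 14.6% and 0% of barcodes held under 1000 counts. Libraries, groups, comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. No comparison was tested, since each group holds 1 library.

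Peaks of Control and Pik3caHR were merged where they overlapped, into 180251 regions. Of these 131857 held a peak of both libraries (shared regions), 9280 only of Control and 39114 only of Pik3caHR. Shared regions held 99.5% of Control counts and 97.4% of Pik3caHR counts. Cells with at least 1000 counts in shared regions were kept. Doublets were removed at the expected rate of 0.8% per 1000 cells by the share of simulated doublets among 50 neighbours, which took 139 Control and 201 Pik3caHR cells and left 4033 and 4816. Counts were weighted by TF-IDF and reduced by truncated SVD to 30 components, the first left out. A graph of 20 neighbours was clustered by the Leiden method at resolution 0.5. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

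Clusters were named from marker lists for basal, luminal (both classes), luminal hormone-sensing, luminal alveolar progenitor, fibroblast, endothelial, pericyte, myeloid, T or NK, B, adipocyte and Schwann cells. A name needed a mean log2 fold of the markers of at least 0.5 over the 25th percentile of clusters, with 5 CPM added, a lead of 0.1 over the next class, and 3 markers up. A cluster whose median depth lay below 1/3 of the library median was left unnamed. Shares have exact Clopper-Pearson intervals of 95%. Classes with at least 200 cells in both libraries were compared.

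Gene positions came from the RefSeq table of GRCm38.p6. Protein-coding genes with 2 kb added at both ends took the counts of overlapping shared regions, and 17203 of 21883 genes had any. The plan was to add 2 kb upstream only and to use transcription start sites, but the table gives no strand, so both ends were used throughout. Values are counts in CPM, scaled to the counts in shared regions, ratios have exact intervals for 2 Poisson counts, and 0.1 CPM was added for list medians. A gene was called at a ratio of at least 1.5 in either direction, an interval that excludes 1 and at least 100 counts in both libraries together. No ratio was given where both libraries held 3 counts or fewer. Besides the 12 marker lists, 11 lists were used, for milk and alveogenesis, FOXO targets, lipid and sterol synthesis, immediate early and dissociation stress, interferon, NF-kB and inflammation, stem and plasticity, COMPASS and PRC2, cell cycle, PI3K pathway and housekeeping genes. Of 261 list genes 260 were matched, Mx1 being the exception. A list's median log2 ratio was placed among 10000 random lists of the same size drawn within 20 bins of accessibility.

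Genes were named by rule. Named first were Pik3ca and Kdm6a, then in each class the 10 genes higher and the 10 lower whose interval bound nearest 1 lay farthest from it, and up to 2 members of each list at each end. For the peaks of Pik3caHR_Kdm6aKO the rule took list members with peaks in only some libraries and the 10 largest gains and losses in number of peaks. Peaks per gene were compared after adding 1, as a mean log2 ratio per list, against random lists matched on Control peaks. Covered length of a gene sums the whole length of every peak that touches the gene with its added 2 kb. It can reach beyond the gene, and 1 peak can count for several neighbouring genes. Peak sets were compared by overlap of at least 1 bp with bedtools 2.31.1. As a check of coordinates, 71.6%, 73.5% and 73.7% of genes had a peak at an end in Control, Pik3caHR and Pik3caHR_Kdm6aKO, against 32.8%, 37.3% and 37.2% with genes moved by 1 Mb.

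The gene comparison was tested on simulated counts, drawn with Poisson error from the same mean of each gene for both libraries. The rates for genes and lists therefore cover counting error alone. They leave out called width and differences between cells, animals or preparations. Of genes given a 2-fold difference, 100% were recovered in all cells, 98% in alveolar progenitor-like, 92% in hormone-sensing-like and 96% in basal-like cells. Unchanged genes that passed numbered 16 of 16908, 24 of 16729, 153 of 14744 and 107 of 15067. Of 100 unchanged lists, 3, 3, 2 and 5 lay outside the central 95% of random lists, and 3 of 100 in the peak comparison. Of 100 artificial doublets added to each library, 67% and 63% were removed.

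Alternatives fixed beforehand were resolution 1.0, no doublets removed or 1.6% per 1000 cells, at least 3000 counts per cell, clustering without regions at list genes, cells thinned to 5000 counts, each library clustered on its own, scaling by the median ratio of genes or by counts at gene ends, gene ends only (1 kb either side), every peak of each library, binarised counts, no minimum or 500 counts per gene, and list members with at least 100 counts. For peaks they were reciprocal overlap of 50%, chromosomes 1 to 19 and X only, peaks at or above the median width, gene ends only and covered bases. Motif shares were planned and not run, as no genome sequence was at hand.

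Some choices were made after the data were seen. These were the score that names clusters, which was revised several times, the doublet score, the comparison on regions of similar width (83639 regions, or 63.4%) and its limit of 25%, set after several limits had been tried, clustering on those regions, counting the low-depth cluster with its leading class, the gene ranking at similar width, the width thresholds for wide peaks, the weight given to covered length of the Kdm6a-deleted library, and the rule that list results outside the central 95% of random lists count as main results.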

Results

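Chromatin accessibility was measured by single-cell ATAC-seq, with 10x Genomics libraries, in mouse mammary epithelial cells. Adeno-Cre virus was given 2 weeks before harvest, 2 glands were pooled per mouse, and cells carrying the GFP that Cre switches on were sorted. There were 3 libraries, 1 per genotype. Control came from LSL-Cas9-EGFP mice, Pik3caHR added the activating Pik3ca H1047R allele, and Pik3caHR_Kdm6aKO also carried floxed alleles of Kdm6a, which encodes a histone H3K27 demethylase. The series title names lineage commitment. The design text of the series describes RNA profiles of tumours, which these libraries are not, and the number of mice per library is not stated. Control held 4887 cell barcodes, 144686 peaks and 83.8 M counts, with a median of 17771 counts per cell. Pik3caHR held 5017 barcodes, 172538 peaks and 70.1 M counts, with a median of 13409. Pik3caHR_Kdm6aKO is used through its 6594 barcodes and 173619 peaks, and levels in this library were not analysed here.

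With 1 library per genotype no difference could be tested, so every value below describes these libraries. Intervals are 95% and cover counting error only, and differences between mice or preparations are not in them. Ratios are Pik3caHR over Control, from counts scaled to each library's total (CPM) in regions with a peak in both libraries. A gene is called higher or lower when its ratio is at least 1.5-fold in either direction with an interval that excludes 1. Each library's counts stop at the edges of its own peaks, so a ratio can move with the length called. The length called may in turn follow accessibility. A smaller ratio at similar width thus does not by itself mark a difference as due to called length. Called length, and the ratio over regions whose longer called length exceeds the shorter by at most 25% (similar width), are therefore given beside the ratios.

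The engineered loci carried peaks in all 3 libraries. Pik3ca on chromosome 3 had 75.9 CPM in Control and 67.0 in Pik3caHR, a ratio of 0.883 (0.835 to 0.934), over 9545 and 9560 called bases. Kdm6a on chromosome X had 74.96 and 72.0 CPM, a ratio of 0.960 (0.909 to 1.01). Kdm6a held 8, 8 and 9 peaks in Control, Pik3caHR and Pik3caHR_Kdm6aKO, covering 8.99, 7.94 and 8.24 kb. Which part of Kdm6a is floxed is not given in the sources used here, so these peaks check nothing about the deletion.

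Hormone-sensing and basal cells took larger shares of the Pik3caHR library, and alveolar progenitor cells a smaller one. Cells like luminal hormone-sensing cells made up 5.01% of 4033 used Control cells (4.36 to 5.73) and 13.1% of 4816 used Pik3caHR cells (12.2 to 14.1), a ratio of 2.62. Basal-like cells made up 7.49% (6.69 to 8.34) and 15.4% (14.4 to 16.5), a ratio of 2.06. Alveolar progenitor-like cells, the luminal class marked by Elf5, Kit and milk protein genes, made up 73.8% (72.5 to 75.2) and 67.8% (66.5 to 69.1). Myeloid-like cells numbered 63 and 31, and 488 and 145 cells stayed unnamed. Across 8 other ways of choosing and clustering cells the hormone-sensing ratio ran from 2.23 to 3.04 and the basal ratio from 1.72 to 2.48. GFP sorting and infection decide which cells enter a library, so these shares are not those of the gland. In Control 14.6% of barcodes held under 1000 counts, against 0% in Pik3caHR, and the unnamed low-depth cluster took 364 Control cells and 30 Pik3caHR cells.

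**Figure D1:**
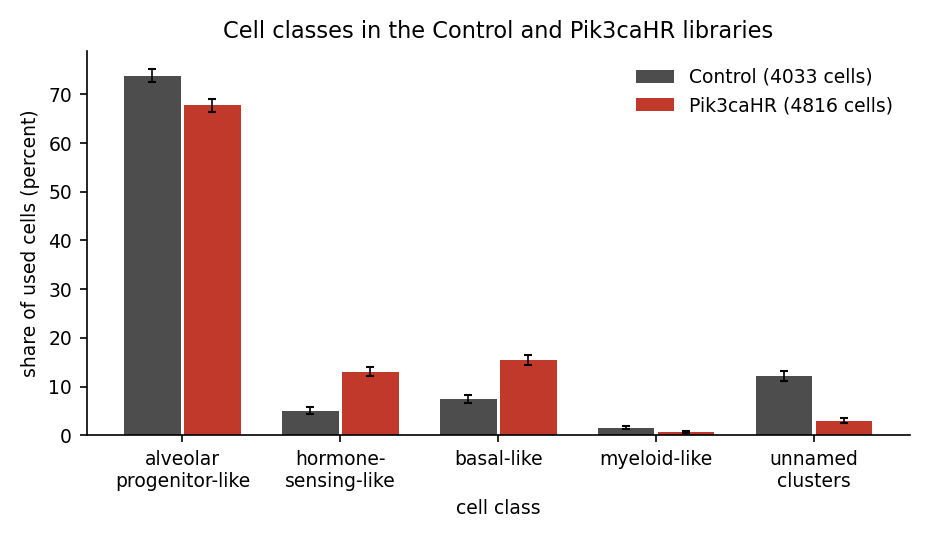
Share of used cells (percent) in each cell class in Control (4033 cells) and Pik3caHR (4816 cells), with 95% Clopper-Pearson intervals for counting error. Hormone-sensing-like cells were 5.01% and 13.1%, and basal-like cells 7.49% and 15.4%.

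Alveolar progenitor-like cells of the 2 libraries lay in separate clusters, while hormone-sensing-like cells shared 1. The largest alveolar clusters held 11 Control and 2798 Pik3caHR cells, and 2735 Control and 45 Pik3caHR cells. A smaller alveolar cluster mixed 232 and 423. Hormone-sensing-like cells formed a single cluster of 202 Control and 631 Pik3caHR cells, although at the finer resolution of 1.0 they too parted by library. Basal-like cells formed a cluster of 102 and 740 cells and a cluster of 200 and 3 cells. Clustering on regions of similar width joined these into 1 basal cluster of 297 and 715 cells and left the alveolar split, with clusters of 2575 and 181, 82 and 2608, and 268 and 429 cells. A cluster mostly from 1 library may be that library rather than a cell type, so the comparisons below use whole classes.

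In alveolar progenitor-like cells, 6 milk genes and the basal keratin gene Krt14 were called higher in Pik3caHR. Tbx3, a gene of the hormone-sensing list, was called lower, and the NF-kB list lay low as a list, with 1 member called. Krt14 went from 34.8 CPM in Control to 69.7 in Pik3caHR, a ratio of 2.00 (1.86 to 2.16), over 8508 and 10362 called bases, or 4.09 and 6.73 CPM per called kb. Its ratio at similar width was 2.06. The milk gene Csn3 went from 15.4 to 30.5 CPM, a ratio of 1.98 (1.77 to 2.22), and 1.83 at similar width. Tbx3 went from 113 to 53.5 CPM, a ratio of 0.473 (0.443 to 0.504), over 12854 and 8077 called bases, with 0.590 at similar width. Of 16929 genes measured, 842 were called higher and 230 lower. At similar width 309 and 127 of 15904 genes were called.

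The milk and alveogenesis list had a median log2 ratio of 0.32 in these cells, above all 10000 random lists of the same size and accessibility (percentile 100), and 0.24 (percentile 100) at similar width. Percentiles of lists are a description of these libraries. Of its 17 measured members 6 were higher, 0 lower and 11 neither. Besides Csn3, the higher members were Csn1s1 (ratio 2.94, 2.07 to 4.23), Cel (2.12), Lalba (1.81), Wap (1.81) and Csn1s2a (1.62, and 1.67 at similar width). Csn1s1, Cel, Lalba and Wap were not measured at similar width. Their called bases were 440 and 1086 for Csn1s1, 3780 and 7849 for Cel, 2556 and 3225 for Lalba, and 1167 and 1762 for Wap. Per called kb, Cel differed little, with 2.99 and 3.04 CPM, while Lalba had 6.25 and 8.96. Members under the threshold with a ratio above 1 at similar width included Trf (1.34, and 1.38), Btn1a1 (1.33, and 1.37) and Slc34a2 (1.246, and 1.28). Muc1 went the other way, with 0.862.

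The NF-kB and inflammation list had a median of -0.22, below all random lists (percentile 0), with the same median at similar width. Cxcl1 was called lower (ratio 0.638, 0.574 to 0.710), over 4581 and 2691 called bases, and 13 of 14 measured members were neither. At similar width Cxcl1 had 0.705, under the threshold. Tnfaip3 (0.737), Icam1 (0.745), Nfkbia (0.809) and Tnf (0.820) lay below 1 with intervals that exclude 1, and Lcn2 (1.14) above. Cxcl10 of the interferon list was called lower at 0.620 (0.545 to 0.704), and 0.638 at similar width, over 2737 and 2680 called bases.

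The basal list had a median of 0.22 (percentile 99.95) in alveolar progenitor-like cells and 0.15 (percentile 99.0) at similar width. Its 13 members were 1 higher, 0 lower and 12 neither. Krt5 (ratio 1.40), Snai2 (1.38), Col17a1 (1.38) and Krt17 (1.27) lay above 1, Trp63 (1.02) and Mylk (1.01) near it, and Oxtr (0.844) and Tagln (0.870) below. Col17a1 had 1.11 at similar width with an interval that includes 1. Krt17 had 1.89 at similar width, past the threshold. The summed basal list took 546 CPM of alveolar progenitor-like cells in Control and 630 in Pik3caHR, a ratio of 1.15 (1.13 to 1.18), over 118 and 141 called kb. Per called kb these were 4.62 and 4.48 CPM, and at similar width the ratio was again 1.15. In cells thinned to 5000 counts the mean was 2.69 basal-list counts per Control cell and 3.10 per Pik3caHR cell, with medians of 2 and 3 and an upper quartile of 4 in both. Means of other lists rose too, such as those shared by both luminal classes (6.71 and 7.37) and housekeeping genes (4.28 and 4.50). Others fell, such as the alveolar progenitor (3.47 and 3.28) and hormone-sensing lists (2.84 and 2.67). On gene ends alone the basal list's median was 0.05 (percentile 91.6).

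The alveolar progenitor list had a median of 0.18 (percentile 99.84), with 4 of 11 measured members higher, 0 lower and 7 neither. It shares 6 of its 12 genes (Elf5, Csn1s1, Csn2, Csn3, Wap and Lalba) with the milk list, and its 4 higher members are among them, so the 2 lists are not separate results here or below. At similar width its median was 0.03 (percentile 83.9). Its summed CPM had a ratio of 0.945 (0.926 to 0.965), on the other side of no difference from its median, with Aldh1a3 (189 and 129 CPM, ratio 0.685) and Kit (137 and 97.8, ratio 0.714) among the members below 1. Kit was called over 23003 and 13680 bases and had 0.936 at similar width, with an interval that includes 1, and Aldh1a3 had 0.745. The hormone-sensing list had a median of 0.11 (percentile 97.6) and 0.06 (percentile 89.2) at similar width, with 0 of 13 members higher, Tbx3 lower and 12 neither. Its summed ratio was 0.947 (0.926 to 0.969), which turned to 1.03 at similar width. The list of genes shared by both luminal classes had a median of 0.06 (percentile 92.5), and 0.10 (percentile 99.25) at similar width, with none of 9 members called. Krt8 (ratio 1.46, and 1.51 at similar width), Krt18 (1.34) and Krt19 (1.24) lay above 1, and Ehf (0.845) and Elf3 (0.894) below.

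**Figure D2:**
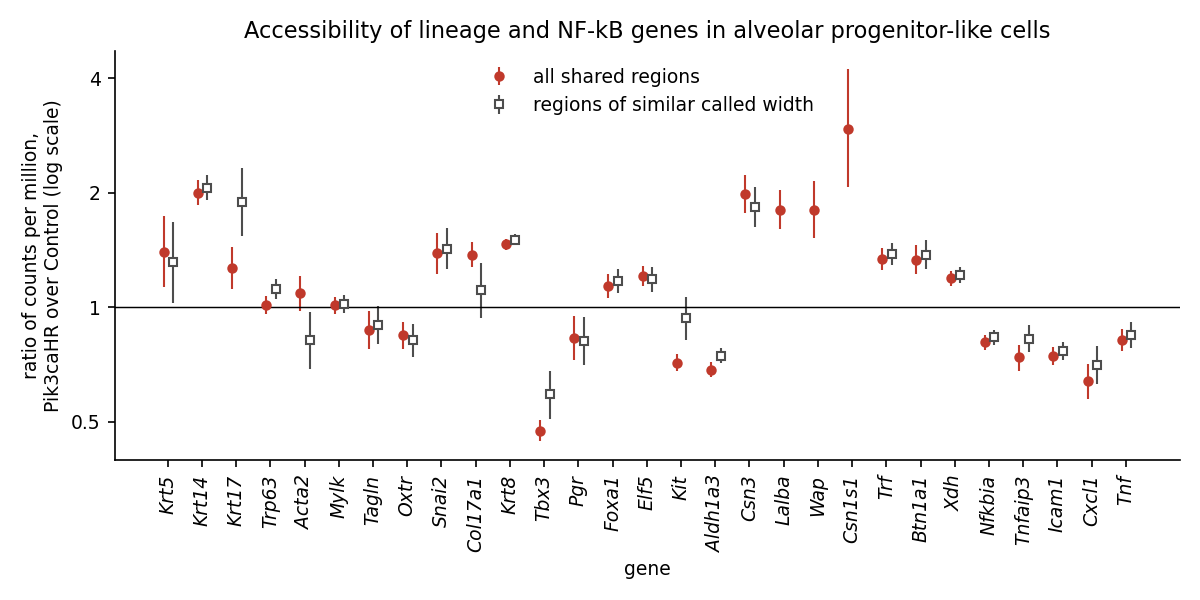
Ratio of CPM, Pik3caHR over Control (log scale), for genes of the basal, luminal, milk and NF-kB lists in alveolar progenitor-like cells, over all shared regions (filled circles) and regions of similar called width (open squares), with 95% counting intervals. Krt14 sits at 2.00 and 2.06, and Tbx3 at 0.473 and 0.590. Genes with no open square were not measured at similar width.

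Of the other lists, the adipocyte list had the largest median in alveolar progenitor-like cells, 0.84 (percentile 99.4), with Lep, Cidec and Pparg higher, 0 lower and 2 of 5 neither. At similar width 3 members were measured, with a median of 0.54 (percentile 98.95). Pparg had a ratio of 1.79 (1.58 to 2.02) and 1.45 at similar width, and Cidec had 1.83 and 1.87. The stem and plasticity list had a median of -0.03 (percentile 49.7), with Lef1 (1.56) higher and 17 of 18 neither. Lef1 had 1.37 at similar width, under the threshold, and Sox10 had 1.42. No member was called in the PI3K pathway list (0.02, percentile 92.4), where Inpp4b had 1.44, or in the FOXO target list (-0.04, percentile 35.6), where Igf1r had 0.718 and Pdk4 0.730. No member was called in the lipid and sterol synthesis list (0.00, percentile 85.7), the immediate early list (-0.06, percentile 19.2), the cell cycle list (-0.06, percentile 35.97), the COMPASS and PRC2 list (-0.06, percentile 30.3) or the housekeeping list (-0.02, percentile 70.0). Fosl2 of the immediate early list had 1.30 and Hspa1a 0.677. The interferon list had a median of -0.07 (percentile 28.3), with Cxcl10 lower and 11 of 12 neither. The other lists of cell types outside the epithelium lay inside the central 95% of random lists. These were fibroblast (0.14, percentile 63.1), endothelial (-0.02, 40.0), pericyte (0.00, 43.4), myeloid (0.10, 87.2), T or NK (-0.09, 18.9), B (-0.03, 42.0) and Schwann (0.04, 41.5). Dcn (2.28), Cdh5 (1.54), Kdr (1.56), Abcc9 (1.57) and Cd3e (3.53) of these lists were called higher and no member lower.

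Among all genes, the 10 ranked highest and lowest by the rule fixed beforehand rested on regions of very different called length. In alveolar progenitor-like cells the highest were LOC108167340, Mrap, Chil4, Tacr1, Abcg3, Trh, Clec2h, Kcnc2, 1700020D05Rik and Tmem252, and Chil4 for example was called over 416 bases in Control and 1581 in Pik3caHR, with 1.27 and 20.5 CPM. The lowest were Evi2b, Gm40892, Pglyrp3, Serpina3g, Dcc, H2-M2, Prss48, C030002A05Rik, Kcnq5 and Morf4l1b. Kcnq5 (ratio 0.322) had 0.697 at similar width, and the value of Prss48 (0.260) turned to 1.37 there. By the same rule at similar width, chosen after the values were seen, the highest genes included Nfam1 (2.997, 2.55 to 3.52), Spp1 (3.07), Chst2 (2.84), Cib3 (3.13), Rnf183 (2.53), Nfasc (2.31) and Bdnf (2.62). Spp1 encodes osteopontin, a secreted glycoprotein, and went from 7.69 to 25.3 CPM over 1601 and 3269 called bases. The lowest included Nr1h5 (0.326, 0.249 to 0.422), Hspb8 (0.399), Traf1 (0.463) and Loxl1 (0.523). Across regions with at least 100 counts, the log2 ratio of counts and the log2 ratio of called widths had a Pearson r of 0.82 in these cells. This correlation is across regions of these libraries, which are not independent replicates.

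**Figure D3:**
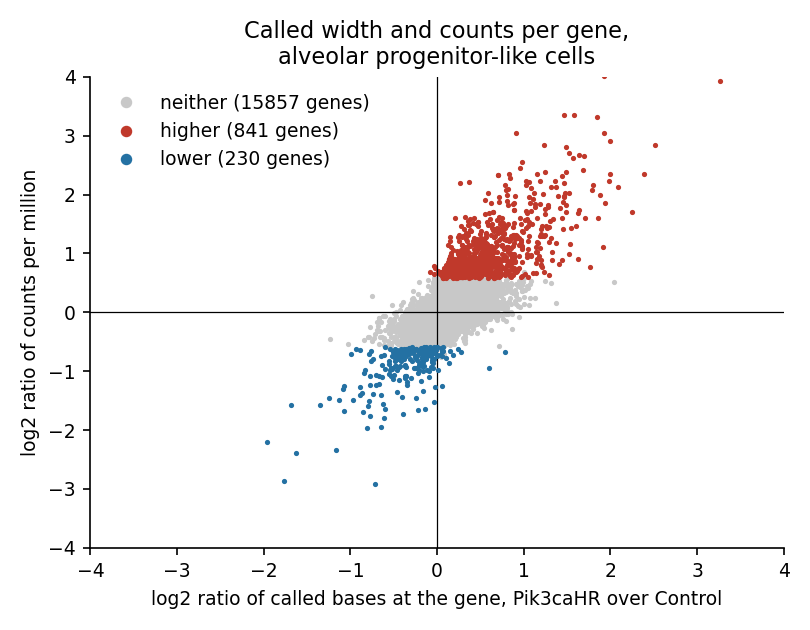
Log2 ratio of called bases (horizontal) and log2 ratio of CPM (vertical), Pik3caHR over Control, for 16928 genes in alveolar progenitor-like cells, each point a gene and 9 genes outside the axes. Genes called higher lie mostly to the right of 0 and genes called lower mostly to the left.

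In basal-like cells, the alveolar transcription factor gene Elf5 was called higher in Pik3caHR, and the alveolar progenitor list lay high as a list. Elf5 went from 22.6 to 39.4 CPM, a ratio of 1.74 (1.30 to 2.31), over 14246 and 17442 called bases, and 1.55 at similar width. On gene ends alone Elf5 had a ratio of 0.403, in the other direction, with an interval that includes 1 (0.0740 to 1.253). Kit had 1.87 (1.20 to 2.99), over 23003 called bases in Control and 13680 in Pik3caHR, with 0.395 and 1.24 CPM per called kb. The alveolar progenitor list had a median of 0.45 (percentile 99.8) and 0.33 (percentile 99.7) at similar width, with 2 of 11 members higher, 0 lower and 9 neither. The summed list took 350 CPM in Control and 400 in Pik3caHR, a ratio of 1.14 (1.06 to 1.23), over 110 and 97.2 called kb, or 3.18 and 4.11 CPM per called kb. The milk list had a median of 0.32 (percentile 98.9), with Cel (2.17) and Elf5 higher and 15 of 17 neither, but 0.13 (percentile 85.2) at similar width. The basal list itself had a median of 0.10 (percentile 95.7) with no member called, Krt14 (0.974) and Krt5 (1.01) near 1, and Trp63 (0.790) and Myh11 (1.37) apart.

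Other list genes called in basal-like cells were Sox11 (3.36, 1.85 to 7.07, and 3.15 at similar width), Zeb1 (1.61), Cdkn2a (1.73), Kdr (2.29), Tnfsf11 (1.66) and Lep (1.74), all higher. Lower were Cxcl1 (0.611), Cxcl10 (0.571), Ifih1 (0.552), Cldn4 (0.656), Msx2 (0.439), Twist1 (0.542), Rgs5 (0.558) and Kcnj8 (0.454). At similar width Tnfsf11 had 1.31 and Cxcl1 0.719, both under the threshold, and the interval of Twist1 (0.558) included 1. The housekeeping list had a median of 0.13 (percentile 97.8) with no member called, which gives a scale for list medians of this size in this class. The Schwann list had -0.54 (percentile 0.750) over 4 members, none called, and -0.20 (percentile 8.34) at similar width. Of 15267 genes, 313 were higher and 194 lower, and at similar width 193 and 156. Among simulated unchanged genes 107 of 15067 also passed in this class, so some of its calls may be counting error alone. First by the fixed rule was 1600014C10Rik, with 31.5 and 275 CPM and a ratio of 8.74 (7.10 to 10.9), over 3200 and 13213 called bases. Gp9 (3.36, and 3.46 at similar width) was also among the 10 highest, and Ttc9 (0.504, and 0.462) among the 10 lowest. At similar width H2-D1 (2.01) was among the highest.

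In hormone-sensing-like cells some list genes were called, in a class where 1.28% of all measured genes were called higher and 1.66% lower. Among simulated unchanged genes 153 of 14744 also passed, so some of these calls may be counting error alone. Krt17 (ratio 2.05, 1.17 to 3.81), Des (1.95), Btn1a1 (1.605) and Cdh2 were higher in Pik3caHR, and Snai2 (0.586, 0.380 to 0.868), Vim (0.555) and Fap (0.628) lower. At similar width Btn1a1 had 1.65, Cdh2 1.64, Snai2 0.602 and Vim 0.564, and Krt17, Des and Fap were not measured. No member of the hormone-sensing list was called, with Esr1 (1.11), Pgr (1.14) and Foxa1 (1.11) within counting error of 1. The summed basal list (ratio 0.995, 0.914 to 1.08) and the summed alveolar progenitor list (0.970, 0.875 to 1.07) did not differ detectably at this depth, with 202 Control cells. The endothelial list had a median of 0.42 (percentile 99.8) with no member called, and 0.37 (percentile 96.1) at similar width. On gene ends alone it was -0.16. The COMPASS and PRC2 list holds Kdm6a and also PRC2 genes such as Ezh2, Eed and Suz12. Its median was -0.14 (percentile 0.5) with no member called and -0.11 (percentile 1.6) at similar width. With binarised counts it turned to 0.021 (percentile 45.0), and with no doublets removed it had -0.081 (percentile 4.97). The interferon list had 0.16 (percentile 98.3) and the Schwann list -0.46 (percentile 1.38) over 3 members, again with no member called. With no doublets removed the interferon list had 0.051 (percentile 81.7) and the Schwann list -0.32 (percentile 3.70), and on gene ends the interferon list had 0.061 (percentile 86.8). Of 14944 genes 192 were higher and 248 lower, and at similar width 127 and 199. The largest by the fixed rule was Fgf13 (7.47, 3.03 to 23.6), over 2688 and 5681 called bases. Lower were Dmrta2 (0.440, and 0.405 at similar width), H3f4 (0.397) and Mroh2a (238 and 142 CPM, 0.597).

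**Figure D4:**
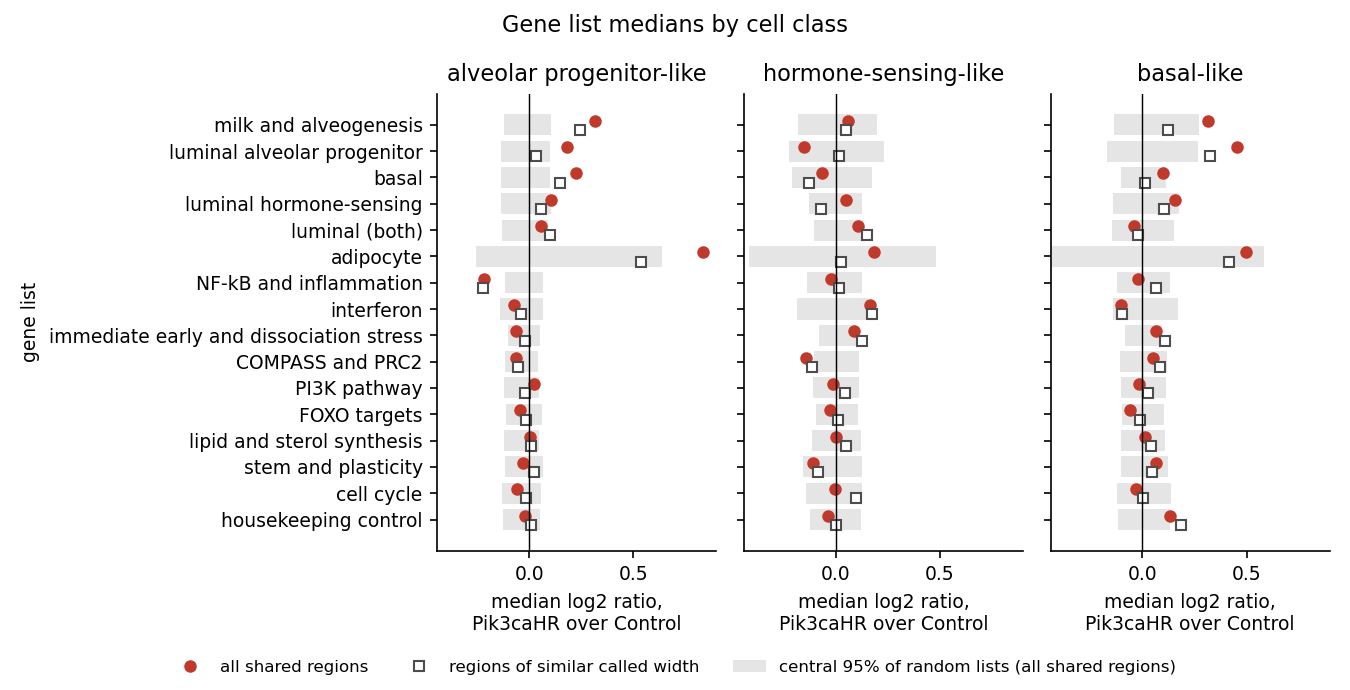
Median log2 ratio of 16 gene lists, Pik3caHR over Control, in 3 cell classes, over all shared regions (filled circles) and regions of similar called width (open squares). Grey bars give the central 95% of 10000 random lists over all shared regions. In alveolar progenitor-like cells the milk list sits at 0.32 and 0.24 and the NF-kB list at -0.22 in both.

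The classes shared part of their calls. Alveolar progenitor-like and basal-like cells shared 102 genes called higher, against 7.85 if independent (385 and 311 calls among 15254 genes), and 24 called lower against 1.40. Alveolar progenitor-like and hormone-sensing-like cells shared 48 higher against 4.66. Called regions and libraries are common to the classes, so part of this excess may come from them. Log2 ratios across genes had a Pearson r of 0.34 between alveolar and basal classes, 0.23 between alveolar and hormone-sensing, and 0.15 between hormone-sensing and basal, with genes not independent replicates. Over all used cells together 899 of 17108 genes were higher and 198 lower, at similar width 266 and 86, and the basal list had a median of 0.39 (percentile 100), where the basal class also took a larger share.

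The peaks of Pik3caHR covered most of those of Control, and the reverse was less so. Of the Control peaks 93.6% overlapped a Pik3caHR peak and 90.2% a Pik3caHR_Kdm6aKO peak. Of the Pik3caHR peaks 77.3% overlapped Control and 85.5% Pik3caHR_Kdm6aKO, and of the Pik3caHR_Kdm6aKO peaks 73.5% overlapped Control and 84.3% Pik3caHR. Of 39114 Pik3caHR peaks absent from Control, 57.4% were present in Pik3caHR_Kdm6aKO. Of 27298 Pik3caHR_Kdm6aKO peaks absent from Pik3caHR, 11.8% were present in Control. Covered length was 137 Mb in Control, 157 Mb in Pik3caHR and 163 Mb in Pik3caHR_Kdm6aKO. Peak numbers and lengths move with depth and with the mix of cells, and neither was measured here for the Kdm6a-deleted library.

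Against Pik3caHR, the Kdm6a-deleted library did not stand apart by number of peaks, the measure fixed first, at genes of the basal, hormone-sensing, alveolar progenitor, milk, NF-kB, interferon or immediate early lists. The basal list had 172 peaks in Pik3caHR and 152 in Pik3caHR_Kdm6aKO (mean log2 ratio -0.03, percentile 33.1), the hormone-sensing list 105 and 124 (0.14, percentile 93.6), the alveolar list 75 and 73 (0.05, percentile 55.5) and the milk list 100 and 107 (0.09, percentile 73.0). The NF-kB list had 66 and 80 (0.14, percentile 92.1), the interferon list 42 and 48 (0.20, percentile 97.3) and the immediate early list 30 and 29 (-0.01, percentile 34.4). By covered length, an alternative measure singled out after its values were seen, the same lists lay farther from random lists. Basal list genes were covered by 160 kb of peaks in Pik3caHR and 127 kb in Pik3caHR_Kdm6aKO, with 12 of 13 members less covered (-0.31, percentile 0). Krt5 had 5.99 and 3.75 kb, Krt14 10.4 and 6.60, Trp63 19.5 and 14.1 and Col17a1 16.6 and 11.03, with Control at 3.65, 7.89, 16.8 and 10.4 kb. Snai2 was the exception, with 2.70 and 3.17 kb. On gene ends the basal list went the other way, with 17 and 19 peaks (0.11, percentile 92.95), and among peaks at or above the median width it had 76 and 67 (-0.12, percentile 6.21). By covered length the hormone-sensing list had 110 and 146 kb (0.38, percentile 99.99), with Pgr at 4.93 and 9.82 kb, Prlr at 21.1 and 29.9, Esr1 at 17.4 and 23.7 and Tbx3 at 8.08 and 16.6. Among peaks at or above the median width this list had -0.03 (percentile 33.2). The alveolar progenitor list had 106 and 137 kb (0.34, percentile 99.9), the milk list 141 and 185 kb (0.26, percentile 99.8), the NF-kB list 121 and 170 kb (0.32, percentile 99.9), with Nfkb1 at 29.2 and 55.01 kb, the interferon list 57.0 and 68.6 kb (0.29, percentile 99.4) and the immediate early list 188 and 216 kb (0.18, percentile 98.3).

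Against Control, the Kdm6a-deleted library had more peaks at genes of the alveolar progenitor, milk and hormone-sensing lists, and fewer at genes of the list shared by both luminal classes. The alveolar progenitor list had 56 and 73 peaks (mean log2 ratio 0.62, percentile 99.85), the milk list 79 and 107 (0.49, percentile 99.2) and the hormone-sensing list 75 and 124 (0.43, percentile 99.4). Their covered lengths were 114 and 137 kb, 110 and 185 kb, and 94.8 and 146 kb. Among peaks at or above the median width the milk list fell to percentile 85.8, inside the central 95%. The same comparison of Pik3caHR with Control gave 0.58 for the alveolar progenitor list (percentile 99.9), 0.40 for the milk list (percentile 98.1) and 0.29 for the hormone-sensing list (percentile 94.4, inside the central 95%), and these comparisons share Control. Peaks touching Ltf summed to 2.04, 7.13 and 14.2 kb in Control, Pik3caHR and Pik3caHR_Kdm6aKO, and those touching Stat5a to 9.63, 10.3 and 24.1 kb. Those touching Cel summed to 4.01, 7.86 and 18.6 kb, the last longer than Cel with its added ends. Csn2 had 0, 2 and 2 peaks, Glycam1 0, 1 and 0, Fabp4 0, 0 and 1, and Ifit3 2, 0 and 3. The immediate early list had fewer peaks than in Control (40 and 29, -0.24, percentile 0) and 182 and 216 covered kb (0.20, percentile 54.97, like random lists). Pik3caHR over Control was likewise lower in immediate early peaks (40 and 30, -0.24, percentile 0). The list of genes shared by both luminal classes had 33 and 22 peaks (-0.25, percentile 0.140) over 163 and 185 kb. This held for number of peaks over gene bodies only. On gene ends the list had -0.06 (percentile 13.2), and by covered length it turned to 0.11 (percentile 24.2). Against Pik3caHR that luminal list had 36 and 22 peaks (-0.31, percentile 0.330) over 178 and 185 kb, and the pericyte list 52 and 42 peaks (-0.25, percentile 1.76) over 50.5 and 47.7 kb.

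**Figure D5:**
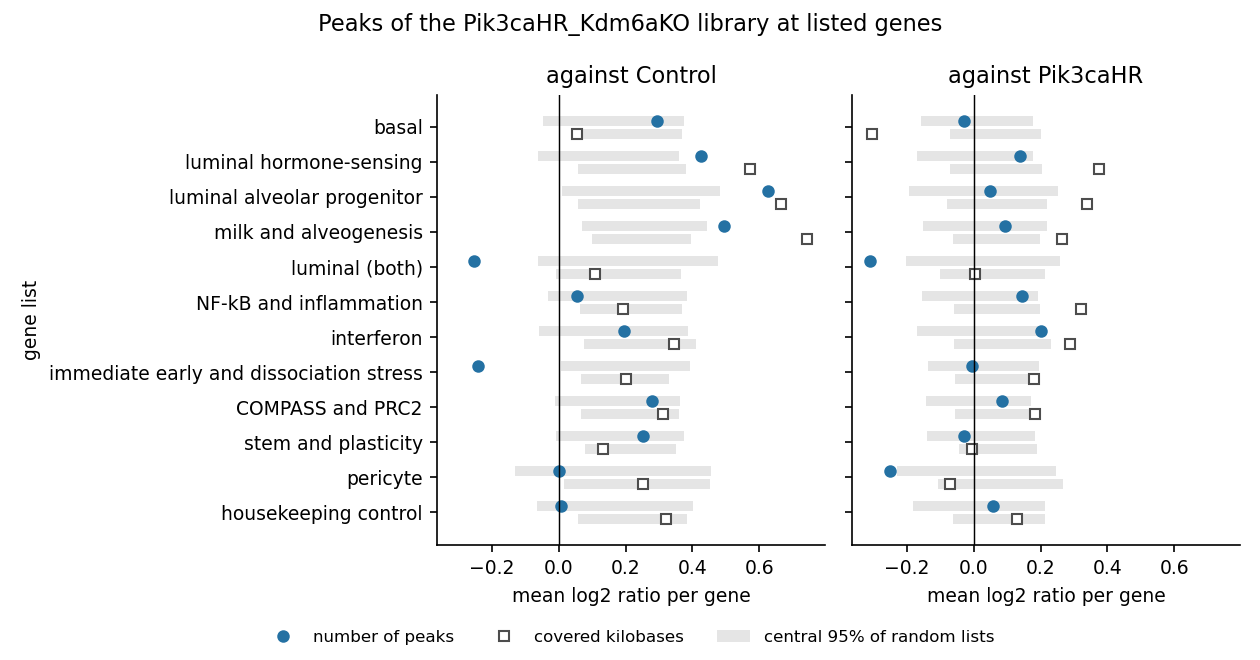
Mean log2 ratio per gene of Pik3caHR_Kdm6aKO over Control (left) and over Pik3caHR (right) for 12 gene lists, by number of peaks (filled circles) and covered kilobases (open squares), with grey bars for the central 95% of random lists. Over Pik3caHR the basal list sits at -0.03 by peaks and -0.31 by covered kilobases, and the hormone-sensing list at 0.14 and 0.38.

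Single genes gained or lost many peaks in the Kdm6a-deleted library. Of 17890 genes with a peak, 4610 had more peaks there than in both other libraries and 1627 fewer. By the same count Pik3caHR had more than both others at 3582 genes and fewer at 1016, and Control more at 1063 and fewer at 6027. The 10 largest gains were at Mast4 (82, 98 and 128 peaks in Control, Pik3caHR and Pik3caHR_Kdm6aKO, over 71.2, 79.5 and 137 kb), Thsd4 (77, 92 and 117), Apc (11, 12 and 33, over 11.1, 11.4 and 27.9 kb), Btbd9, Nrxn3, Pde10a, Itgav (16, 18 and 33, over 17.3, 16.9 and 56.4 kb) and the overlapping Gm37013, Gm38666 and Gm38667. The 10 largest losses were at Zmiz1 (59, 61 and 23), Dclk1, Csmd1, Efna5, Dpp10, Ralgds, Kirrel, Vps37b, Rac1 (9, 9 and 2) and Rtn4. At Zmiz1 the fewer peaks were longer in sum, with 94.0, 109 and 197 kb, and at Rac1 13.4, 18.3 and 27.3 kb. These sums can include parts of peaks beyond the gene. Peaks of at least 10 kb numbered 114, 165 and 255 in Control, Pik3caHR and Pik3caHR_Kdm6aKO. The widest peak of Pik3caHR_Kdm6aKO spanned 93265 bp at Apol8 and Myh9 on chromosome 15, where Control had 19 peaks over 72374 bp. Its next widest covered 49716 bp at Cdh1 and 42875 bp at Cd9, where Control had 8 peaks over 43455 bp and 9 over 35182 bp.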

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

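The alternatives on regions of similar width and on the low-depth cluster were chosen after the results were seen, and the others beforehand. Kept under every alternative were the milk and NF-kB lists in alveolar progenitor-like cells (percentiles 99.99 to 100 and 0 to 1.02), the alveolar list in basal-like cells (99.3 to 100), the share of hormone-sensing-like cells in Pik3caHR, and the alveolar and hormone-sensing lists of the Kdm6a-deleted library over Control. Of planned values, 26 of 42 class shares stayed within their intervals and 16 moved, 122 of 142 list results stayed, 17 weakened and 3 reversed, and of 3452 values of single genes 3315 stayed, 39 became stronger, 97 weaker and 1 reversed. Of list results that were inside the central 95%, 562 of 592 stayed so and 30 left it. Of 195 named genes called, 193 kept their call under either scaling, 191 with at least 3000 counts per cell, 180 with no doublets removed and 154 with binarised counts. Of those measured, 185 of 189 kept it with every peak, 115 of 145 on gene ends, where 1 turned, and 96 of 128 at similar width, where 2 turned. No paired analysis was possible because each group holds 1 library. Motif alternatives were not run. Depth limits the hormone-sensing and basal classes most, where 92% and 96% of simulated 2-fold differences were recovered. Unless stated, the cause of a difference below was not tested. "Median" stands for the median log2 ratio of a list, Pik3caHR over Control, with its percentile in brackets.

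With at least 3000 counts per cell, alveolar progenitor-like cells were 81.7% of Control, and basal-like cells 9.87% of Control and 17.2% of Pik3caHR. With thinned cells the alveolar shares were 83.1% and 70.3%, and with each library on its own the basal share of Pik3caHR was 18.6%. Counting the low-depth cluster as alveolar gave 82.9% of Control, by construction. With no doublets removed, Control held 71.2% alveolar, 5.92% hormone-sensing and 10.5% basal cells, and Pik3caHR 66.1% alveolar and 18.1% basal. With removal doubled these were 76.2%, 4.21% and 6.50%, and 70.7% and 14.4%.

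With no doublets removed, medians in hormone-sensing-like cells were -0.081 (4.97) for COMPASS and PRC2, -0.32 (3.70) for Schwann and 0.051 (81.7) for interferon, and 0.091 (95.5) for housekeeping in basal-like cells. With list members of at least 100 counts the milk median in basal-like cells was 0.13 (89.8).

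With binarised counts the summed basal list in alveolar progenitor-like cells had a ratio of 1.10. Medians in hormone-sensing-like cells were 0.021 for COMPASS and PRC2, reversed, 0.23 (96.4) for endothelial and 0.14 (96.7) for interferon, and the hormone-sensing median in alveolar progenitor-like cells was 0.079 (94.9). Genes higher were 515 of all cells (main 899), 474 alveolar (842), 67 basal (313) and 36 hormone-sensing (192), and genes lower 57 basal (194) and 32 hormone-sensing (248). Binarising caps the count of a cell at 1, so fewer counts enter.

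With every peak of each library the summed basal list in alveolar progenitor-like cells had 1.19. Medians were 0.93 (95.9) for adipocyte in alveolar progenitor-like, 0.095 (94.6) for housekeeping in basal-like and 0.12 (92.1) for interferon in hormone-sensing-like cells. Genes higher were 532 in basal-like (313) and 411 in hormone-sensing-like cells (192), where regions called in Pik3caHR alone enter.

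With gene ends only, summed ratios were 1.18 for the basal list and 0.857 for the hormone-sensing list in alveolar progenitor-like cells and 1.06 for the milk list in basal-like cells. Medians in alveolar progenitor-like cells were 0.87 (96.1) for adipocyte, 0.047 (91.6) for basal and -0.029 for hormone-sensing, the last reversed. The endothelial median in hormone-sensing-like cells reversed to -0.16, and interferon had 0.061 (86.8) there. Basal-like cells had 0.10 (94.0) for housekeeping and 0.12 (76.7) for milk, and all cells 0.073 (96.8) for hormone-sensing. Elf5 in basal-like cells reversed to 0.403. With scaling by gene ends the summed basal and hormone-sensing lists in alveolar progenitor-like cells had 1.20 and 0.984.

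With a minimum of 500 counts fewer genes are tested. Higher were 509 in all, 431 in alveolar, 40 in basal and 23 in hormone-sensing cells, and lower 129, 139, 32 and 14 (main 198, 230, 194 and 248).

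On regions of similar width, genes higher were 266 in all, 309 in alveolar, 193 in basal and 127 in hormone-sensing cells, and lower 86 in all and 127 in alveolar cells. The summed hormone-sensing list in alveolar progenitor-like cells reversed to 1.03. Medians in alveolar progenitor-like cells were 0.031 (83.9) for the alveolar and 0.055 (89.2) for the hormone-sensing list, in basal-like cells -0.20 (8.34) for Schwann and 0.13 (85.2) for milk, and in hormone-sensing-like cells 0.37 (96.1) for endothelial. Prss48 in alveolar progenitor-like cells reversed to 1.37 (main 0.260) and Serpina11 in basal-like cells to 0.749 (main 3.55).

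For the Kdm6a-deleted library, covered kilobases in place of peaks gave 0.20 for immediate early and 0.11 for luminal (both) over Control and 0.0027 for luminal (both) over Pik3caHR, all 3 reversed, and -0.070 for pericyte over Pik3caHR. Gene ends gave -0.065 and -0.11 for luminal (both) over Control and Pik3caHR, and 0 for pericyte over Pik3caHR, where no difference was left. Peaks at or above the median width gave -0.17 (3.58) for luminal (both) and -0.057 (28.7) for pericyte over Pik3caHR and 0.41 (85.8) for milk over Control.

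Overlap of Control peaks by Pik3caHR and Pik3caHR_Kdm6aKO was 94.2% and 91.0% among wide peaks and 79.6% and 73.4% with reciprocal overlap. Overlap of Pik3caHR peaks by Control and Pik3caHR_Kdm6aKO was 78.2% and 86.5%, and 66.7% and 71.7%. Overlap of Pik3caHR_Kdm6aKO peaks by Control and Pik3caHR was 74.6% and 85.1%, and 61.1% and 71.3%. Reciprocal overlap is stricter by construction.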

Other observations

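Of the tests in this part only the clustering on regions of similar width had its prediction written before its result was seen. The other 5 were chosen after, and all are tests of patterns found in the same data, so that what they leave open is a hypothesis.

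Alveolar progenitor-like cells of Control and Pik3caHR lay in separate clusters, with 89.5% of them in clusters at least 90% from 1 library, and at resolution 1.0 this held for 100% of hormone-sensing-like cells too. On regions of similar width 88.7% (87.8 to 89.4) of alveolar progenitor-like cells stayed so, so larger differences in called width are not needed for the split. Smaller differences in called length remain in those regions, so called width as the whole cause is not excluded. Depth per cell within the called peaks is excluded as the whole cause, since 90.1% (89.3 to 90.8) stayed so in thinned cells. Thinning came after peaks were called, so an effect of depth on called edges is not covered by it and is not excluded. Both intervals treat cells as independent, although cells entered as whole clusters, so they do not give the uncertainty of the split. Genes called in alveolar progenitor-like cells on regions of similar width were followed into the other classes. They had at least 500 counts in alveolar progenitor-like cells and 100 in the other class. In hormone-sensing-like cells 138 genes kept 2.24% (-9.12 to 16.9) of their median log2 difference. In basal-like cells 167 genes kept 24.1% (11.05 to 39.2), with genes resampled. For these genes the values argue against a shift of equal size in every class. They were picked by their alveolar ratios in these same data, so smaller values elsewhere are expected in part. The split itself is not tested by them, so a shift common to the classes is not excluded as its cause. A weaker part may be common to the classes, since the lower calls among these genes kept 39.4% (13.5 to 62.7) in hormone-sensing-like cells, where the higher calls kept -9.69%. Alveolar progenitor-like and basal-like cells also shared 102 higher calls against 7.85 if independent. Those shared calls are from all shared regions, where called edges are common to the classes and may bring part of the excess. Smaller differences in called length remain open as a cause of the split. So do the genotype and any difference between animals or preparations, acting on the classes alike or unequally. With 1 library each, genotype and differences between animals or preparations could not be told apart.

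Krt14 was higher in alveolar progenitor-like cells of Pik3caHR. Basal cells, doublets or free fragments among them would have to reach 35.4% for the Krt14 excess, and the other basal markers showed a median of 9.97% of the excess this share would bring, with 11 of 12 below the needed level by their intervals. Snai2 was the exception, with 74.6%. On regions of similar width the ratio was 2.06 (1.91 to 2.23). The called lengths of Krt14 lay within the limit for similar width, so this ratio kept their difference. It therefore cannot decide on called width, which is not excluded as the whole cause. Counts per called kb were also higher in Pik3caHR, so added length with the same counts per kb would not bring the whole excess. The genotype, or a difference between animals, could account for the Krt14 excess and was not separated.

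More genes were called higher than lower in alveolar progenitor-like cells of Pik3caHR, with 78.5% of calls higher. On regions of similar width 70.9% (66.4 to 75.1) of calls were higher, so larger differences in called width are not needed for the excess. That interval treats genes as independent. Smaller differences in called length remain in those regions, so called width as the whole cause is not excluded. Called width could account for part, since of 842 higher calls 444 were measured on those regions and 236 were still called. Other causes stay open too, since depth was not tested for these calls and genotype cannot be told apart from differences between animals or preparations.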
